A study of Bombyx mori with 3 samples.

How the data were processed

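Fat body RNA of phoxim-fed and control silkworm larvae was hybridised to 3 two-colour arrays, 1 per biological replicate per the labels. Per the labels' protocols, total RNA was amplified with T7 RNA polymerase and labelled with Cy5 or Cy3 during cDNA synthesis. Each array file held 24288 spots in 48 printing blocks, with 23229 gene probes of 1 spot each, 677 positive and 382 negative control spots. The intensity values of both channels were used as deposited. Their scanner, image software and background method are not given in the sources used here. Blank spots centred near 0 and some values lay below 0, so the intensities were treated as already background-subtracted. Per the file headers, the ratio column is phoxim over control on each array, and it differs from the plain quotient of the intensities, so the authors had normalized it by a method not given in the sources used here. The deposited log2 value table was compared with the log2 of these ratios row for row and differed by at most 5e-09. Its medians were 0.01, -0.02 and 0.05, which leaves its centring method unknown and its scale and direction known. Text codes of the files marked control spots and intensity classes.

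The labels and the series description state that no dyes were swapped, but the file header of replicate 2 names the control RNA as Cy5 and the treated RNA as Cy3. The header was followed. Hex control spots were bright in the Cy3 column and near 0 in the Cy5 column on all 3 arrays, so the columns hold the dyes they name. The labelled order was run as an alternative.

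The design had foreseen separate foreground and background columns. As only subtracted intensities were used, normexp (offset 50) was applied to them directly, followed by a loess fit within each array in which control spots had weight 0. Probes were kept where at least 1 channel exceeded the 95th percentile of negative control spots on all 3 arrays, which left 6154 probes. That percentile was 46.9, 101.0 and 31.8 in Cy5 and 188.3, 307.1 and 175.7 in Cy3 for replicates 1, 2 and 3. Ratios were turned to phoxim over control, and their mean was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05. The array pairs a treated with a control sample and acts as the block. The SD of a probe between arrays had a median of 0.49, and the number of arrays limits the precision. Bounds written as "at least" are used where a group was not well above background on any array. They set the mean of the brighter group against the dimmer group's values or the lowest signal above background, per channel after loess and Aquantile, and remain open to dye bias because only 1 array of 3 has the other dye order. Spots at 99% or more of a channel's maximum were taken as saturated, and no gene whose ratio is given by name was saturated.

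A list of 33 groups of genes was fixed before the data were examined, as patterns on symbols and descriptions, and 29 had at least 5 measured genes. The brightest probe stood for a gene. Lists were tested with limma's camera against all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation called 0 lists. Fry, which tests a list against no change and not against other genes, called 0 in a given direction and 1, apoptosis and autophagy, without regard to direction. An estimate of that correlation from 3 arrays is itself imprecise. Camera with an estimated correlation also takes its degrees of freedom from the arrays, so p-values rise even where the estimate is below the preset value. For apoptosis and autophagy the estimate was -0.0017, and the unadjusted camera p was 0.094 against 0.0050 with the preset. Its 0 calls therefore cannot show that correlation between genes accounts for the preset calls. Patterns also took in members by wording alone, and 51 such members were removed in an alternative chosen after seeing the data. Named genes followed a rule also fixed beforehand. It takes the 10 largest increases and decreases past the threshold. With fewer than 5 in a direction it is filled to 5 by smallest p from genes with a single gene ID and the same sign on all arrays. It adds the 2 members with the smallest p of each list with at least 3 measured genes. For lists that did not pass, some of these members are not printed below. Counts over a list alone were adjusted within that list and not across the 29 lists, so single members may pass by chance. Further members are named where a count over the list alone includes them, or as examples chosen after their values were seen. These examples are Attacin1, moricin, lebocin, the cecropin D probes, Cyp6b29, a lower P450 probe (sw20316), Hsp70 and Iap. The saturated storage proteins, caspase-1 and the second apoptosis inhibitor 5 probe belong to them as well.

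Of the gene probes, 1271 carried 1 gene ID, 45 several and 21913 none. Of the last, 14669 had a homology text. Of 1039 gene IDs, 1013 matched the reference gene table (assembly ASM3026992v2) by ID and 10 through an mRNA accession, and 16 kept the name in the files. Other probes are named by probe ID and the description in the files, which often comes from another species. No coordinates were used, because the files name no genome build.

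The limma step was tested on simulated data with the spread between arrays of the 6154 probes and 200 changed probes. The changed probes were 2-, 4-, 8- or 16-fold in equal parts. Changes of 2-fold were called in 3.8% of cases, 4-fold in 76.0% and 8-fold in 94.9%. The larger simulated changes ease the adjusted threshold for the others, so these shares hold only for such a mix. In the real data, the probe sw18561 at 6.59-fold (unadjusted p = 1.5e-04 with limma) had an adjusted p of 0.28. In simulated lists of 30 genes shifted by 0.5 and independent of each other, camera called 100% of shifted and 1.5% of unshifted lists. Estimated correlations of the lists called in the real data reached 0.51 (muscle), so these 2 shares do not carry over to them. Alternatives covered the background correction, the normalization, the filter, the test, array weights, each array left out and the gene list test. Added after seeing the data were a dye term, the labelled dye order of replicate 2, print-tip loess, the files' intensity classes as filter, lists without wording matches and peptides without gloverins. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.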

Results

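Gene expression in the fat body of the domestic silkworm Bombyx mori (strain p50, both sexes) was measured after feeding with phoxim. The fat body is the insect organ that stores nutrients and secretes most hemolymph proteins, and phoxim is an organophosphate insecticide, a class of compounds that block acetylcholinesterase. Larvae on day 3 of the last instar ate mulberry leaves dipped in phoxim at 4 µg/mL, control larvae ate leaves dipped in water, and fat bodies were dissected after 24 h. Each of 3 two-colour arrays carried RNA of treated and of control larvae with the same replicate number, and each experiment used 30 larvae. The question addressed was which genes respond to the insecticide in this organ. Of the 23229 gene probes on an array, 43.2%, 27.0% and 44.5% exceeded the background of the blank spots in the Cy5 channel of replicates 1, 2 and 3, and 24.9%, 18.9% and 27.2% did so in the Cy3 channel, so these shares follow the dye. A total of 6154 probes, counted as 6050 genes, were bright enough to be tested. Only 778 of these probes carried 1 gene ID, and a probe without a single gene ID or gene model counted as its own gene.

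The labels place phoxim RNA in Cy5 on every array, whereas the file header of replicate 2 places it in Cy3. The header was followed, and every value below is phoxim over control on the log2 scale. Of 8 yeast control RNAs, 3 reached the Cy5 ceiling of replicate 2. Across the other 5, the ratios of replicate 2 in header order correlated with the mean of the other arrays at r = 0.95 (Spearman's rho = 0.90, exact permutation p = 0.025 for r, two-sided, across RNAs and not across samples). Turned as labelled, replicate 2 would correlate negatively at r = -0.27 with replicate 3 across the tested probes.

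No probe reached the threshold for a difference between phoxim and control. With limma, 0 of 6154 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.28, so the count of probes changed at least 2-fold was 0 as well. At an unadjusted p under 0.05 there were 673 probes (377 higher and 296 lower in phoxim RNA), where chance would give 307.7. The genes named in the next paragraph therefore did not pass. The ratios of replicates 1 and 3 correlated at 0.35 across probes, those of replicates 2 and 3 at 0.27 and those of replicates 1 and 2 at 0.03. Replicates 1 and 3 share a dye order and replicate 2 has the reverse, and the fit held no dye term. These values therefore cannot separate agreement between replicates from a dye effect. All 3 arrays gave the same sign for 2172 probes, or 35.3%, against 25% by chance, and 43 probes were at least 2-fold higher and 19 at least 2-fold lower on each array. Most of the 43 lacked control signal above background on some arrays. Each of the 19 had control signal above background on all 3 arrays, and some lacked phoxim signal on some arrays. The 2 counts are thus unequally affected by the background.

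Among probes with a single gene ID and the same sign on all arrays, the 5 genes with the smallest p-values in each direction follow. Each gene was taken by its brightest probe. Titin2, a giant elastic protein of the sarcomere, had a log2 ratio of 2.65 ± 1.14 (SD, n = 3), although its control level exceeded background on 1 of 3 arrays. LOC778468, described as heat shock protein 1, stood at 2.66 ± 1.68, LOC693038 (p270) at 2.28 ± 0.94 with 1 control array above background, and Cb10 (wing disc-specific protein) at 1.56 ± 0.58. Far, a fatty-acyl reductase that makes fatty alcohols, was not well above background in any control sample and was at least 1.68-fold higher in phoxim RNA. On the lower side, Hsp20.1, a small heat shock protein, had a log2 ratio of -1.88 ± 0.95 (SD, n = 3), the peroxiredoxin Jafrac1 -1.55 ± 0.62 with 2 phoxim arrays above background, the 25 kDa proteasome subunit LOC732876 -1.51 ± 0.55, pyruvate kinase (LOC692450), the last enzyme of glycolysis, -1.20 ± 0.48, and the RNA-binding protein TBPH -1.13 ± 0.26. Each of these 10 genes had the same sign on all 3 arrays, and their adjusted p-values lay between 0.28 and 0.33.

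Genes of antimicrobial peptides were lower in phoxim RNA as a group. The list held 10 measured genes, with 2 probes each for gloverin 4 and cecropin D counted apart. Its mean lay 1.24 log2 units below that of all other genes, and camera gave an adjusted p of 6.8e-06. With an estimated correlation between genes (0.45), a test with few degrees of freedom here, the adjusted p was 0.65. The call also ended without the gloverin probes (-0.81, camera adjusted p = 0.084) and with replicate 2 turned as labelled (-0.46, 0.076). Both alternatives were chosen after the data were seen. The shifts were -0.58, -1.17 and -1.96 in replicates 1, 2 and 3. Adjusted over the list alone, 5 genes fell, 0 rose and 5 did not pass, and adjusted over all probes none of them passed. All 5 were gloverins, glycine-rich antibacterial proteins of moths. The gloverin 3 probe fell by 1.88 ± 0.79 on the log2 scale (adjusted p = 0.0076 over the list alone), the gloverin 2 probe fell by 1.72 ± 0.65 (adjusted p = 0.0076) and the gloverin 1 probe fell by 1.38 ± 0.91 (adjusted p = 0.026), with phoxim levels above background on 2 of 3 arrays for gloverin 1. Both probes for gloverin 4 fell as well, by 1.56 ± 0.95 and by 1.62 ± 1.28. These probes target closely related genes and may read each other's transcripts, since the files assign several gene IDs to the gloverin 2 and gloverin 3 probes. Among the peptides that did not pass, Attacin1 (described as nuecin) had values of 0.69, -2.75 and -3.07 on the 3 arrays, moricin (Mor) 0.44, -0.57 and -2.71, and lebocin (LOC693033) 0.30, -1.49 and -1.35. The cecropin D probes differed, with -1.11, -0.22 and -1.03 (BGIBMGA000017) against 1.50, -0.04 and -0.15 (sw18189). Of the list, 9 members had a mean below 0, and sw18189 was the only 1 above. Pattern receptors and melanisation genes, another immune list, did not pass (19 genes, shift 0.05, camera adjusted p = 0.99). Their smallest p-values were those of a prophenoloxidase activating proteinase (sw18465, 0.72 ± 0.45, above background on 2 arrays in either RNA) and the peptidoglycan receptor PGRP-S1 (-0.77 ± 0.58). Serine protease inhibitors had a shift of 0.25 (14 genes, camera adjusted p = 0.099).

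**Figure D1:**
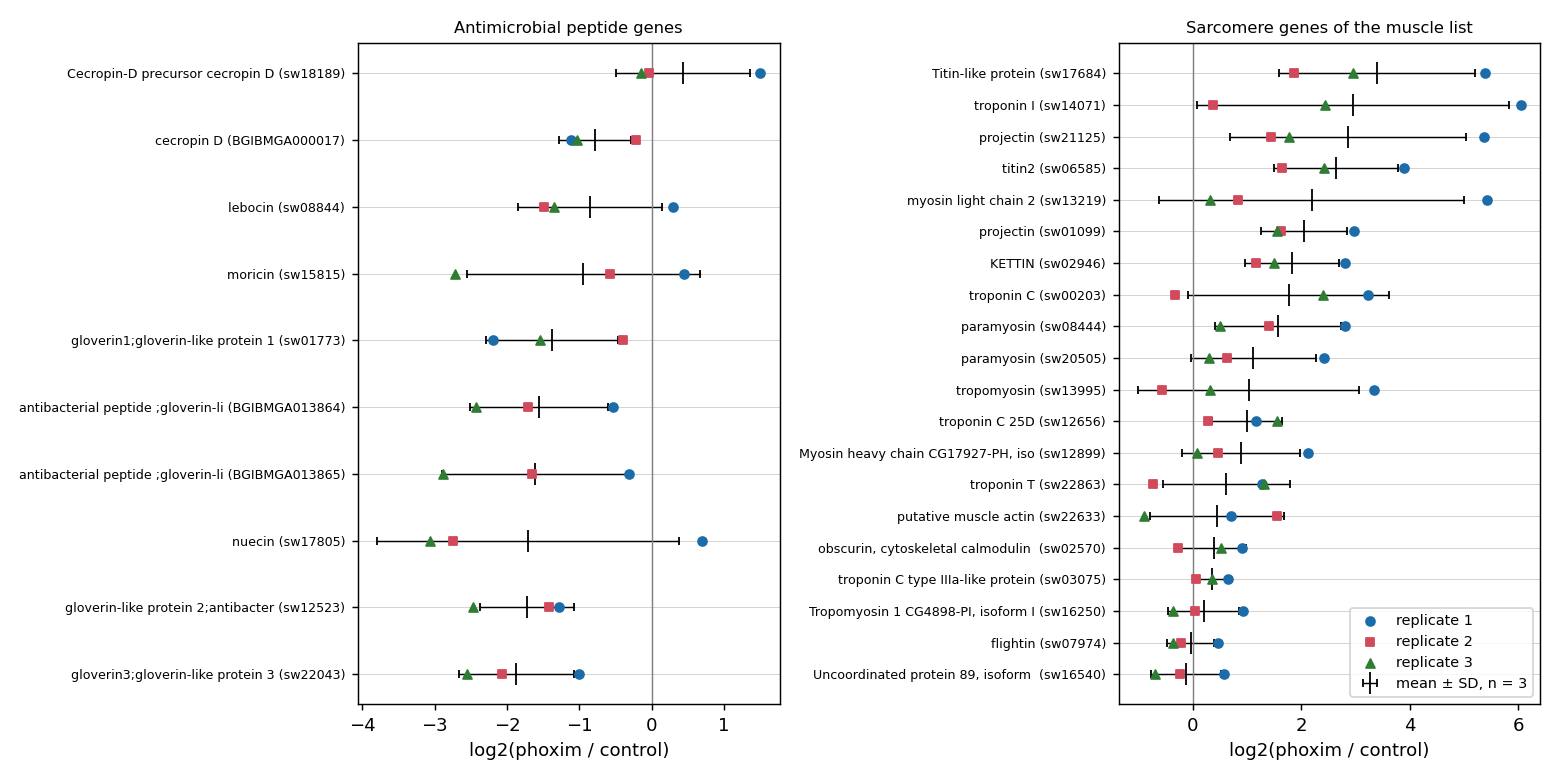
Log2 ratios of phoxim over control (horizontal axis) for the 10 antimicrobial peptide genes and for 20 sarcomere genes of the muscle list (vertical axes, gene description and probe); coloured symbols are the 3 arrays, and black ticks with bars are the mean ± SD. The gloverin probes lie below 0 on each array, and titin-like, projectin and kettin probes lie above 0 on each array, with the highest values in replicate 1.

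Muscle markers, fixed as a check on other tissues in the dissected material, were higher in phoxim RNA. The muscle list of 33 genes had a shift of 0.84 (camera adjusted p = 3.3e-04), and with an estimated correlation (0.51) the adjusted p was 0.65. The shifts were 1.68, 0.37 and 0.46 in replicates 1, 2 and 3, and without replicate 1 the shift was 0.42 (camera adjusted p = 0.042). Adjusted over the list alone, 7 genes rose, 1 fell and 25 did not pass, and adjusted over all probes none of them passed. The genes that rose were Titin2, a titin-like gene (sw17684, 3.40 ± 1.81), probes for projectin (sw01099, 2.05 ± 0.80, and sw21125, 2.87 ± 2.17), kettin (sw02946, 1.83 ± 0.87), paramyosin (sw08444, 1.58 ± 1.16) and a muscle LIM protein (LOC692826, 2.08 ± 1.74). The projectin probes sw01099 and sw21125 carry no single gene ID and were counted apart, so a gene may be counted more than once. Projectin and kettin are giant proteins that link thick filaments to the Z-disc, and paramyosin forms the core of thick filaments in insects. Background limits these values, since the control level of the sw01099 probe exceeded background on 1 of 3 arrays and those of sw21125, kettin and paramyosin on 2 of 3. The gene that fell (sw17482, -1.18 ± 0.16, phoxim above background on 2 arrays) encodes a cofilin-type actin-binding protein and had entered the list through the wording of its description. Without such members, which were removed after the data were seen, 22 genes had a shift of 1.37 (camera adjusted p = 4.1e-09, and 0.68 as the adjusted p with an estimated correlation of 0.71). No other tissue list with at least 5 genes passed. The shifts were -0.37 for Malpighian tubule and transport (13 genes, camera adjusted p = 0.13), 0.20 for midgut (9 genes, 0.43), 0.12 for hemocytes (16 genes, 0.72), -0.07 for testis and ovary (21 genes, 0.82) and -0.01 for epidermis and trachea (23 genes, 0.83). The epidermis value averages shifts of 0.26, -1.17 and 0.89 on the 3 arrays, and that list passed in opposite directions without replicate 2 (0.57, camera adjusted p = 0.0096) and without replicate 3 (-0.45, 0.017).

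**Figure D2:**
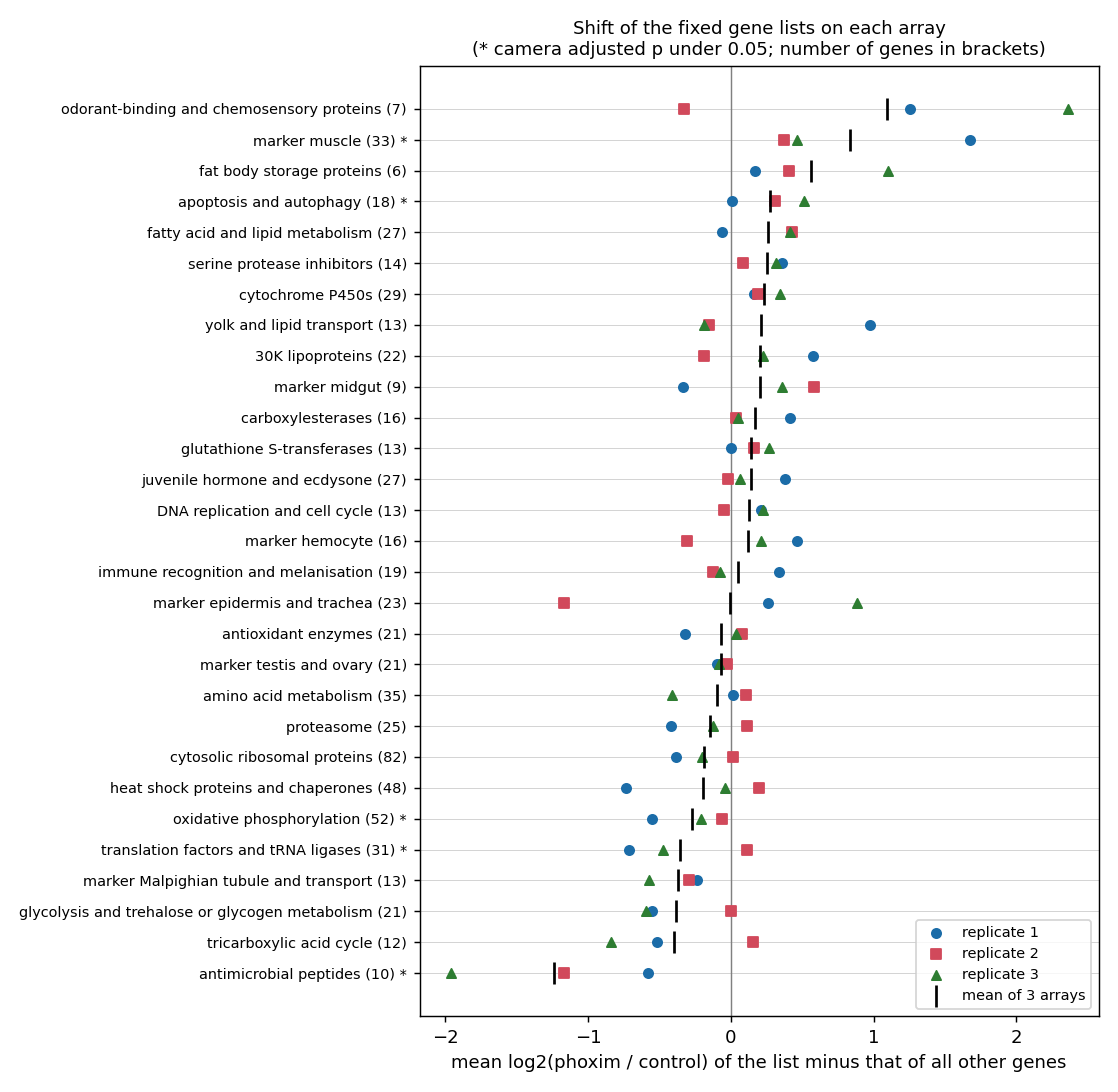
Shift of each fixed gene list against all other genes (horizontal axis, mean log2 ratio of phoxim over control of the list minus that of the others) for the 29 lists tested (vertical axis, number of genes in brackets); symbols are the 3 arrays, black ticks their mean, and an asterisk marks a camera adjusted p under 0.05. Antimicrobial peptides lie lowest at -1.24, and among the 5 lists with an asterisk the muscle list lies highest at 0.84.

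Lists of translation and energy genes gave small negative shifts whose calls ended with an array left out and under other processing or list membership. Translation factors and tRNA ligases, 31 genes, had a shift of -0.36 (camera adjusted p = 0.0099, and 0.65 as the adjusted p with an estimated correlation). The shifts were -0.71, 0.12 and -0.48 in replicates 1, 2 and 3. The call ended without replicate 1 (-0.18, camera adjusted p = 0.35), with median centring (-0.29, 0.062) and with a dye term (-0.24, 0.097). Adjusted over the list alone, 2 genes fell, 0 rose and 29 did not pass. Asparaginyl-tRNA synthetase (sw20364), which charges asparagine tRNA, fell by 1.32 ± 0.38 on the log2 scale with 2 phoxim arrays above background. Initiation factor 4B (sw03287), which helps ribosomes to bind mRNA, fell by 1.42 ± 0.53. For both the adjusted p was 0.047 over the list alone and 0.30 over all probes. Oxidative phosphorylation, 52 genes, had a shift of -0.27 (camera adjusted p = 0.027, and 0.65 as the adjusted p with an estimated correlation). The shifts were -0.55, -0.06 and -0.21 in replicates 1, 2 and 3, and 0 genes passed adjusted over the list alone. The call ended without replicate 1 (-0.13, camera adjusted p = 0.54), with the deposited ratios (-0.21, 0.27) and with median centring (-0.19, 0.16). It also ended without background correction, without the dim filter, with array weights and with a dye term. The members with the smallest p-values were a subunit of the vacuolar proton pump (VATPc, -1.20 ± 0.57), which acidifies compartments and is no part of the respiratory chain, and subunit c of ATP synthase (sw21875, -0.99 ± 0.36). Without the vacuolar pump genes, which had matched by wording, 44 genes had a shift of -0.21 (camera adjusted p = 0.095). The shifts of these lists were largest in replicate 1, where the muscle shift was largest too. Cytosolic ribosomal proteins had a shift of -0.19 (82 genes, camera adjusted p = 0.13), with RpL17 at -1.14 ± 0.71. Glycolysis and sugar storage genes had a shift of -0.38 (21 genes, 0.057), with fructose bisphosphate aldolase (LOC778467) at -1.46 ± 0.93, and the tricarboxylic acid cycle one of -0.40 (12 genes, 0.080). Without a member matched by wording the latter passed, with a shift of -0.49 over 11 genes (camera adjusted p = 0.032, and 0.68 as the adjusted p with an estimated correlation).

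The apoptosis and autophagy list passed with a small positive shift, and that call was not stable. Its 18 genes had a shift of 0.28 (camera adjusted p = 0.029, and 0.65 as the adjusted p with an estimated correlation), and 16 of them had a mean above 0. The shifts were 0.01, 0.31 and 0.52, so that replicate 1 showed next to none. The call ended without replicate 2 (0.26, camera adjusted p = 0.059), without replicate 3 (0.16, 0.31), with the deposited ratios (0.28, 0.065), median centring (0.27, 0.079), no dim filter (0.09, 0.20) and a dye term (0.29, 0.052). Of its members, 0 passed adjusted over the list alone. The leading members were 2 probes for apoptosis inhibitor 5 (sw16145, 0.85 ± 0.04, and sw12623, 0.71 ± 0.25, with 2 control arrays above background), the inhibitor of apoptosis gene Iap (0.69 ± 0.47) and a probe for cell division cycle and apoptosis regulator 1 (sw09065, 0.74 ± 0.06). The first 3 encode proteins that hold back cell death, and sw16145 and sw09065 varied least between arrays within the list. The probe for caspase-1 (sw04417), a cell death protease, was at -0.07 ± 0.70, with phoxim above background on 2 arrays.

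No list of detoxification enzymes passed. The 29 cytochrome P450 genes, oxidases that act on many insecticides, had a shift of 0.23 (camera adjusted p = 0.16). Adjusted over the list alone, 1 gene rose, 0 fell and 28 did not pass. The gene that rose was a P450 resembling cyp-32B1 (sw15262), with an adjusted p of 0.043 over the list alone and 0.29 over all probes. It was not well above background in any control sample and was at least 1.58-fold higher in phoxim RNA. The largest P450 value was 3.29 ± 2.27 for LOC100127115, with 5.39, 0.89 and 3.61 on the 3 arrays (adjusted p = 0.055 over the list alone). Cyp6b29 stood at 1.07 ± 0.29, and a CYP6AE probe (sw20316) was lower at -1.30 ± 1.15. Of the P450 list, 9 genes were higher and 4 lower on all 3 arrays. The 13 glutathione S-transferase genes had a shift of 0.14 (camera adjusted p = 0.41), with GSTo2 at 0.70 ± 0.41 and a probe described as glutathione synthetase 4 (sw12179) at 1.10 ± 0.37 with 1 control array above background. The 16 carboxylesterases had a shift of 0.17 (camera adjusted p = 0.25), with an antennal esterase (sw09098) at 0.47 ± 0.04. No member of either list passed adjusted over the list alone. UDP-glycosyltransferases (1 gene measured), ABC transporters (3 genes), cholinergic signalling genes (0) and silk gland markers (3) were too few for a test. Of the ABC transporters, the smallest p-value was that of a subfamily C gene (sw05268, -0.55 ± 0.50), and of the silk gland markers that of the fibroinase gene Bcp (-0.36, -0.51 and -2.13 on the 3 arrays).

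**Figure D3:**
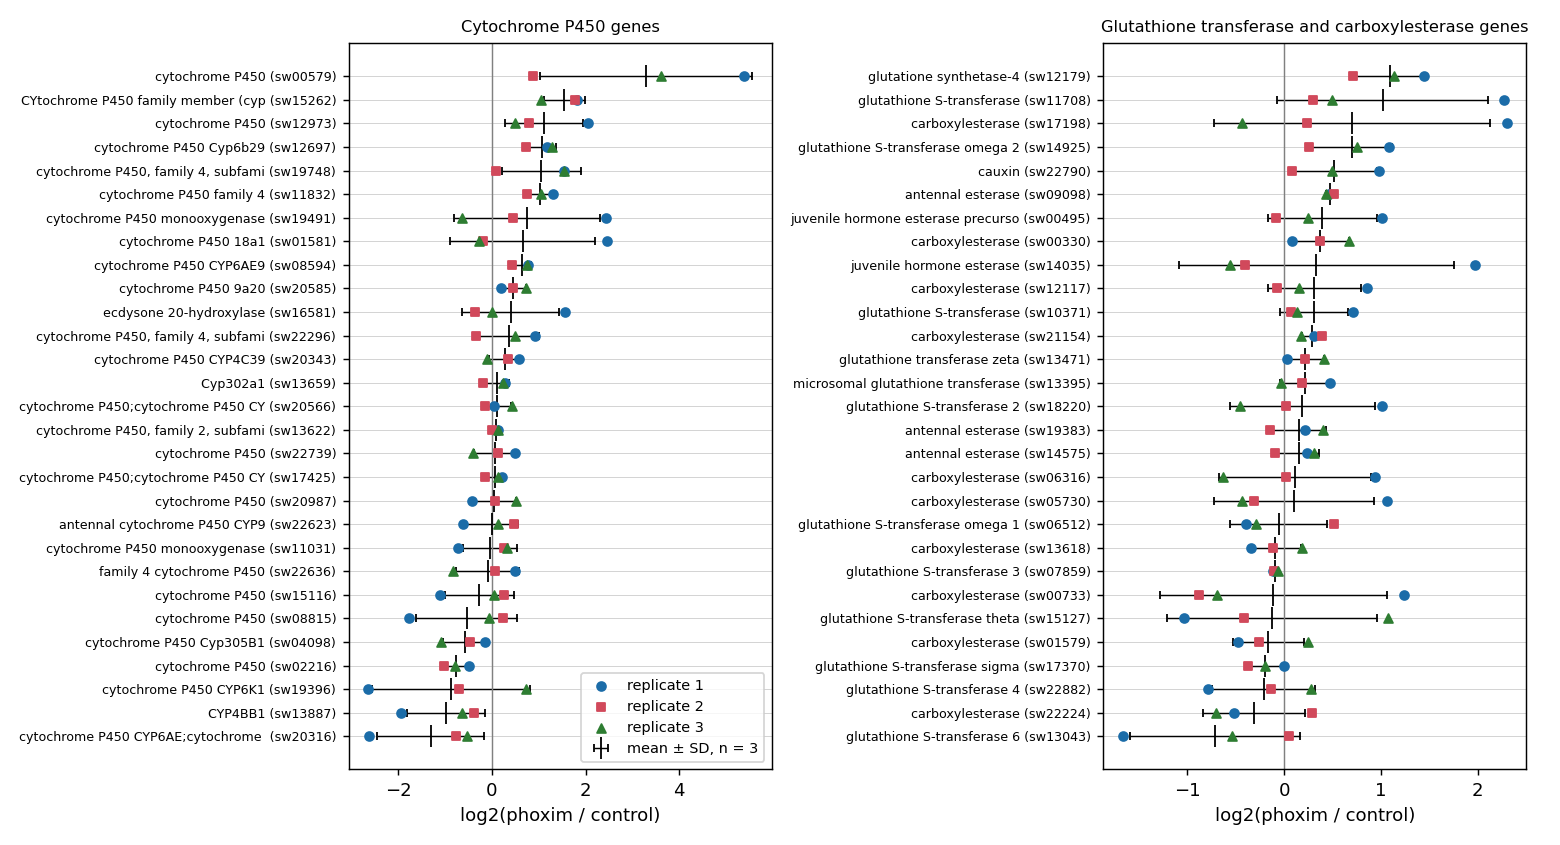
Log2 ratios of phoxim over control (horizontal axes) for the 29 cytochrome P450 genes and for the 13 glutathione S-transferase and 16 carboxylesterase genes (vertical axes, gene description and probe); coloured symbols are the 3 arrays, and black ticks with bars are the mean ± SD. Values lie on both sides of 0, and the highest mean is 3.29 for the P450 probe sw00579 (LOC100127115).

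No list of stress and protein quality genes passed. Heat shock proteins and chaperones had a shift of -0.19 (48 genes, camera adjusted p = 0.15), antioxidant enzymes one of -0.07 (21 genes, 0.83) and the proteasome one of -0.14 (25 genes, 0.43). Hsp70 had a mean of 1.22 ± 0.71, with 2 control arrays above background, and did not pass. Thioredoxin peroxidase (LOC733003), which removes peroxides, had a log2 ratio of -1.13 ± 0.52 and did not pass either. The median of the antioxidant list (0.04) and that of the immune receptor list (-0.02) had the opposite sign to their means.

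No list of secreted and stored fat body products passed, and saturation limits what these lists can show. Storage proteins had a shift of 0.56 (6 genes, camera adjusted p = 0.43), the 30K lipoprotein list one of 0.21 (22 genes, 0.15, or 0.29 with 17 genes and 0.094 without members matched by wording), and yolk and lipid transport genes one of 0.21 (13 genes, 0.40). Adjusted over the list alone, 1 storage protein rose, a methionine-rich hexamerin (sw13517), by 2.34 ± 1.65 (adjusted p = 0.034, and 0.33 over all probes). The major storage proteins Sp1, arylphorin (Sp2) and an arylphorin subunit (sw06703) were saturated on at least 1 array in both RNAs. Ratios on saturated arrays may be compressed, so their means do not show the size of a change. The same holds for 4 members of the 30K list (sw19281, sw22776, LP3 and sw19103). Fatty acid and lipid genes had a shift of 0.26 (27 genes, 0.41), and 1 member rose adjusted over the list alone, a fatty acid desaturase (sw11269, 2.58 ± 1.26). Its adjusted p was 0.031 over the list alone and 0.28 over all probes, and its control level exceeded background on 2 of 3 arrays. A triacylglycerol lipase (sw22288) had a mean of 1.64 ± 0.99. Amino acid metabolism had a shift of -0.10 (35 genes, 0.61), with tyrosine hydroxylase (sw13482), the first enzyme of dopamine synthesis, at 1.69 ± 1.29 and 1 control array above background. Hormone genes had a shift of 0.14 (27 genes, 0.55), with the ecdysone receptor EcR at 1.83 ± 1.33 and 1 control array above background, and juvenile hormone diol kinase (sw04517) at -1.07 ± 0.33. DNA replication and cell cycle genes had a shift of 0.13 (13 genes, 0.41). Odorant-binding and chemosensory proteins, small carriers of hydrophobic ligands, had a shift of 1.09 over 7 genes (camera adjusted p = 0.11), with shifts of 1.25, -0.33 and 2.36 on the 3 arrays. Adjusted over the list alone, 1 of them rose, CSP5 (described as chemosensory protein 4), with 1.87 ± 1.27 and 1 control array above background. Its adjusted p was 0.045 over the list alone and 0.33 over all probes.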

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

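The alternatives with a dye term, with replicate 2 turned as labelled, with print-tip loess, with the files' intensity classes, without wording matches and without gloverins were chosen after seeing the data. The count of 0 probes past the threshold held under every alternative fit at an adjusted p under 0.05 and at 0.1, and was 161 (158 of them at least 2-fold) at an unadjusted p under 0.01. Aquantile after loess leaves ratios as they are, and the deposited ratio column and value table hold the same values and were run together. Without the replicate block, 0 probes and 5 lists passed, and no call changed. Median centring moved the median of all probes to 0.24, against 0.00 with loess, and list shifts are relative to other genes. The share of tested probes with a mean above 0 was 68.7% with median centring, 57.1% with the deposited ratios and 50.3% with loess.

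The number of lists called was 5, and it was 2 with median centring and with a dye term, 3 without the dim filter, 10 with replicate 2 turned as labelled, 0 with an estimated correlation and 0 with directional fry. Leaving out an array gave 3 to 11 lists, with 11 without replicate 2 and 3 without replicate 1. The number of tissue lists called was 1, and 2 without replicate 2, 2 without replicate 3, 2 in the labelled order, and 0 with an estimated correlation and with fry. Mean array agreement was 0.218, from 0.0278 without replicate 3 to 0.355 without replicate 2, and 0.0182 in the labelled order. The cause of these differences was not tested, except that the labelled order changes the sign of 1 array by construction.

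Antimicrobial peptides kept a negative shift in all 22 alternatives, from -1.57 to -0.46. The call ended with an estimated correlation (shift -1.24, adjusted p = 0.65), in the labelled order (-0.46, 0.076) and without gloverins (-0.81, 0.084), which leaves 5 genes. Fry asks another question, whether a list mean differs from 0, and its adjusted p was 0.44 for the peptides (mean -1.20) and 0.62 for muscle (mean 0.87). Muscle markers kept a positive shift in all 22, from 0.42 without replicate 1 to 1.37 without wording matches, and the call ended with an estimated correlation (0.84, adjusted p = 0.65). The remaining lists kept their direction and lost their call more often, and directional fry called none of them. Fry without a direction had an adjusted p of 0.010 for apoptosis and was under 0.05 for no other list. The tricarboxylic acid cycle list, not called at -0.40, was called without wording matches (-0.49, 0.032), without replicate 2 (-0.68, 0.0096) and in the labelled order (-0.50, 0.0041). Translation genes lost it with median centring (-0.29), an estimated correlation (-0.36), a dye term (-0.24) and without replicate 1 (-0.18, against -0.60 as the other extreme over the arrays left out). Oxidative phosphorylation lost it without background correction (-0.28), with the deposited ratios (-0.21), median centring (-0.19), no dim filter (-0.17), array weights (-0.22), an estimated correlation (-0.27), a dye term (-0.22), without wording matches (-0.21) and without replicate 1 (-0.13, with -0.38 at the other extreme). Apoptosis genes lost it with the deposited ratios (0.28), median centring (0.27), no dim filter (0.0924), an estimated correlation (0.28), a dye term (0.29, adjusted p = 0.052), the labelled order (0.0715), the intensity classes (0.30) and without replicates 2 or 3 (0.26 and 0.16, with 0.41 without replicate 1). Epidermis markers, not called in the report at -0.01, were called at 0.57 without replicate 2, at -0.45 without replicate 3 and at 0.77 in the labelled order, and replicate 2 alone had a shift of -1.17. The 2-fold changes simulated at this spread were mostly missed, so changes of that size were not detectable here. The shares called for larger changes depend on the simulated mix, so larger changes may have been missed too.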

Other observations

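All tests in this part were chosen after the results they bear on had been seen. Of the 62 probes at least 2-fold changed in one direction on each array, several described as p260 stood beside titin and projectin, with means of 2.72 (sw18561) and 1.58 (sw09763), each with 1 control array above background, and, for sw17762, a value that is at least 2.62-fold higher, since no control sample was well above background. These probes were chosen after their values were seen, and none passed with limma. A carbamoylphosphate synthase probe (sw12783) had -1.74, -2.13 and -1.87 on the 3 arrays. In the deposited ratios, 46 probes with an intensity class were above 2 and 14 below 0.5 on all 3 arrays, where independent arrays would give 4.5 and 0.97. With the sign of replicate 2 turned, these counts were 11 and 0. In place of the 62 probes, turning replicate 2, replicate 3 or both gave 16, 4 and 13. Of 44 pathways named in the files with at least 10 measured genes, none passed camera. Pyruvate metabolism came nearest (14 genes, shift -0.47, adjusted p = 0.066).

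Muscle markers were higher in phoxim RNA on each array, most of all in replicate 1. With a dye term the shift was 0.72 (camera adjusted p = 9.5e-04 with the preset correlation and 0.78 with an estimated one). The reversed dye order rests on replicate 2 alone (shift 0.37), so a dye effect stays open. Muscle carried along in the dissection of treated larvae stays open. Of 20 sarcomere genes 18 had a mean above 0, but all 20 belong to the muscle list and restate its shift, with medians of 1.70 for thick and 0.81 for thin filament genes. The thick filament medians were 2.81, 1.00 and 0.52 and the thin filament medians 1.22, 0.06 and 0.84 in replicates 1, 2 and 3, so that their order differs between arrays. A response of muscle genes to phoxim would raise the same genes, was not tested and stays open. A larger share of muscle RNA in treated extracts could also bear on the lists that were lower, which was not tested. Of the lists called lower, translation and oxidative phosphorylation were lowest in replicate 1, whereas antimicrobial peptides fell least there (-0.58).

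Antimicrobial peptide genes were lower in phoxim RNA. With a dye term the shift was -1.22 (camera adjusted p = 2.1e-05 with the preset correlation and 0.78 with an estimated one). The reversed dye order again rests on replicate 2 alone (shift -1.17), so a dye effect stays open. Signal shared between gloverin copies may account for part of the group, since without gloverins the shift of the other 5 genes was -0.81 (camera adjusted p = 0.084), which leaves this open. A lower immune tone under phoxim and a stronger immune stimulus in the control pools would look alike in a ratio, and neither was tested.

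The dye order of replicate 2 differs between its header and its label. If the array had been hybridised as labelled, its yeast control RNAs should follow those of the other arrays, yet turned that way the 5 unsaturated ones correlated at r = -0.95 (exact permutation p = 0.025, two-sided), which argues against the label. This assumes that the control RNAs were added to treated and control samples in the same way on every array. Control RNAs tied to the dye would have similar Cy5 over Cy3 ratios on all arrays. The negative correlation argues against that for the 5 as a set, although Y5 was brighter in Cy5 on all 3 arrays.

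With 3 paired arrays there are 4 sign patterns, too few for a share under 0.05. The count of probes at an adjusted p under 0.05 was 0 in all 4 (highest other 0). At an unadjusted p under 0.05 it was 673, reached by 1 of 4 patterns, and 297 at most in the others. The real pattern called 5 lists and the highest other 10, so that 3 of 4 patterns called as many. The pattern with 10 turns replicate 2 and is also the split by dye, and with a dye term 2 lists were called. The muscle list had a camera adjusted p of 3.3e-04 in the real pattern, 0.0041 with replicate 2 turned and 1.4e-05 with replicate 3 turned, so that a false pattern gave it a smaller p. That pattern keeps the muscle shifts of replicates 1 and 2 (1.68 and 0.37), so it is no comparison without a muscle shift. Antimicrobial peptides had 6.8e-06 in the real pattern and 0.0071 with replicates 2 and 3 turned.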
